A study of Mus musculus with 4 samples.

How the data were processed

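Total RNA from glomeruli of male mice was hybridised to 1 Affymetrix mouse 3' expression array (45101 probe sets) for each of 4 groups: WT control, GC-A KO control, WT ALDO and GC-A KO ALDO. The groups came from the sample titles. Per the labels, every mouse was uninephrectomised, the control treatment was a 2% ethanol infusion with a normal diet, and the ALDO treatment was an aldosterone infusion with a 6% salt diet for 3 weeks. Whether the RNA on an array came from a single mouse or a pool, how the glomeruli were isolated, and the dates of preparation and scanning are not given in the sources used here.

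The deposited values were probe set intensities on a linear scale, 1 column per array, and the submitters' processing notes name Affymetrix Expression Console. The algorithm, its background correction, detection calls and software version are not given in the sources used here. In the values themselves, all were above 0, and the mean after leaving out the highest and lowest 2% was 500.003 on each array, so each array had been scaled to a common trimmed mean before deposit. Scaling of this kind sets the average signal equal and would hide a change of the whole transcriptome. No scanner files were used here.

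Intensities were transformed as log2(intensity + 16), which keeps dim probe sets from giving very large differences and understates the change of low genes. Genes were named from the array's annotation table: 34958 probe sets had 1 gene symbol, 932 had several and 9211 were not listed in it (64 of the 45101 were Affymetrix controls, left out). Only probe sets with 1 symbol were used for genes. Entrez identifiers of 34754 of them (99.4%) were found in a RefSeq gene table of the mouse assembly GRCm38.p6, through which 0 symbols changed. That table was used only for names and for the order of neighbouring genes, and no coordinates are given. The probe set with the highest mean over the 4 arrays stood for its gene, which left 18193 genes, and the 9097 in the brighter 50% by mean (log2 value of 8.04 or more, an intensity of about 247) were counted and described.

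There was 1 array per group, so no p-value, standard error or other replicate error was computed. Each comparison (KO against WT under either treatment, ALDO against control in either genotype, and the difference between the ALDO effects) is a log2 difference, with a count of genes at 2-fold or more. The number of arrays limits the precision of every value. In place of replicates, the next-brightest probe set of each gene past 2-fold was compared with the brightest, which shows how probes behave on the same RNA and nothing about the spread between animals. Correlations and overlaps across genes were given only for pairs of comparisons that share no array. Signal of 18 probe sets for spiked-in control RNA and the ratio of 3' to 5' probe sets of beta-actin and Gapdh described technical spread and RNA quality.

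The 30 gene lists, the rule for naming genes, the comparisons and the alternative settings were fixed before the data were examined; 5 further lists and the tests of explanations in the closing section were written afterwards. For each list and comparison, the median log2 difference of the measured members among the 9097 genes was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. Lists with fewer than 5 measured members (neutrophil, lymphocyte, erythroid and NADPH oxidase) were not placed, which left 26. Lists below percentile 2.5 or above 97.5 were said to stand apart. Genes within a list are correlated, so the percentile describes these arrays and is no test of the conditions. Some lists share genes, such as Lcn2 in the neutrophil and kidney injury lists. Members without a named probe set were not analysed here. Named genes were the 10 with the largest positive and the 10 with the largest negative difference of each pair of arrays, and 6 of either sign for the difference of effects, leaving out clone and model names and genes with another bright probe set of the opposite sign, and for each list up to 2 of its highest and 2 of its lowest members. Npr1, Npr2, Npr3, Nppa and Nppb were always named.

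The steps were tested on simulated data, on arrays whose noise had the spread of the genes' differences of effects between the real arrays, and KO control was compared with WT control (9097 genes). As the data hold no spread between animals, the simulation shows that the steps work and gives no rate of false calls for real mice. Of 50 genes changed at each size, the 2-fold rule called 1 at 1.5-fold, 20 at 2-fold, 46 at 3-fold and 45 at 4-fold, where 0, 2, 4 and 5 had left the brighter 50% through their own change, and it called 0 of 8908 unchanged genes. Of 200 unchanged lists of 15 genes 9 (4.5%) fell outside the central 95%, and all 50 lists shifted by 0.5 were placed higher. Alternatives were quantile normalization, centring each array on its median, no low-signal filter, the brightest 25% of genes, the mean of all probe sets of a gene, and pseudocounts of 1 and 64. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.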

Results

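Gene expression was measured in total RNA from the glomeruli of male mice, with 1 Affymetrix mouse array for each of 4 groups. The RNA also held bright transcripts of tubules, as described below, so a difference may come from glomerular or tubular cells. Wild-type (WT) mice and mice with a systemic knockout of guanylyl cyclase A (GC-A KO, written KO), the receptor for atrial and B-type natriuretic peptide encoded by Npr1, had all had a kidney removed. The control treatment was an infusion of 2% ethanol with a normal diet, and the ALDO treatment was an infusion of the mineralocorticoid aldosterone with a 6% salt diet for 3 weeks. The 4 groups were WT control, KO control, WT ALDO and KO ALDO. The trimmed mean intensity was 500.003 on each array, and the array medians over all probe sets were 89.5, 97.7, 91.9 and 103 in that order. With 1 array per group there was no replicate and no test of any difference, so differences are given as log2 values between 2 arrays, and the number of arrays limits their precision. Of 18193 genes, the 9097 with the highest mean over the 4 arrays were counted. A gene list was said to stand apart when its median difference lay outside the central 95% of 10000 random lists of the same size and matched mean expression, and 80 of 130 such placements did, against 6.5 if genes were independent.

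The targeted gene was read first. The probe set of Npr1 had an intensity of 92.6 in WT control, 108 in KO control, 60.5 in WT ALDO and 23.4 in KO ALDO, all under the intensity of 247 at the low end of the genes counted. Its place relative to the deleted part of the gene is not given in the sources used here, so these values did not check the genotype labels. Nppa and Nppb, which encode atrial and B-type natriuretic peptide, were also dim, with 42.4, 50.1, 3.76 and 42.2 for Nppa and 78.8, 95.8, 48.1 and 79.0 for Nppb. Npr3, the natriuretic peptide clearance receptor, had 1051, 994, 1183 and 1088, and Npr2, the receptor for C-type natriuretic peptide, had 774, 589, 736 and 668. The list of natriuretic peptide and cGMP pathway genes did not stand apart between genotypes, with medians of 0.01 under control treatment and 0.09 under ALDO. It stood higher under ALDO in WT (median 0.17, close to the limit) and in KO (median 0.35, percentile 99.97), where 10 of its 11 measured members were above 0, led by the soluble guanylyl cyclase subunit Gucy1a2 at 0.84 and the cGMP-dependent kinase Prkg1 at 0.69. With dim genes kept neither median stood apart (0.13 in WT and 0.15 in KO), and the WT median also did not with the mean of all probe sets (0.08) or a pseudocount of 1 (0.17).

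KO control was set against WT control to compare the genotypes without aldosterone and salt. Lcn2, a lipocalin secreted by injured tubules and neutrophils, had the largest difference, with an intensity of 76.5 in WT control and 1497 in KO control (log2 difference 4.03, or 3.47 with a pseudocount of 64, since the WT control value is below the array's median). Macrophage and monocyte markers were higher together: all 15 measured members were above 0, 9 of them by 2-fold or more, with a median of 1.13 (percentile 100). They were led by the complement gene C1qb (2.31, intensity 145 to 781) and by Cd74, the MHC class II invariant chain (1.62), with Csf1r (0.31) and Cd14 (0.53) lowest. Heat shock genes were lower, with all 12 members below 0, a median of -0.27 (percentile 0), and Hspa1b at -1.50 and Hspa1a at -1.42. In all, 88 genes were higher and 16 lower by 2-fold or more.

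After Lcn2 and C1qb, the genes highest in KO control were Spink8 (2.27), the prostaglandin D synthase Ptgds (2.12), the tight junction protein Cldn4 (1.91), D17H6S56E-5 (1.89), the potassium channel subunit Kcne1 (1.87), the glutamine transporter Slc38a3 (1.76), the leukotriene C4 synthase Ltc4s (1.72) and Wfdc17 (1.66). The lowest genes were the glucuronosyltransferase Ugt2b38 (-2.01, intensity 26588 to 6569), the carboxylesterase Ces1g (-1.94), the organic anion transporter Slc22a7 (-1.76), Myrf (-1.67), Cyp2d12 (-1.64), Angptl7 (-1.44), the D-amino acid oxidase Dao (-1.21), Sgip1 (-1.15) and the pair Hspa1a and Hspa1b, near-identical copies whose probe sets are best read together. Ugt2b38, Slc22a7, Myrf, Cyp2d12 and Angptl7 were brightest on the WT control array, so a peculiarity of that single array is not separated from genotype. In the order WT control, KO control, WT ALDO and KO ALDO, Ugt2b38 had 26588, 6569, 5543 and 4512. Myrf had 1523, 469, 557 and 317 in that order.

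Immune and injury lists stood higher in KO control. The median of the kidney injury genes was 1.17 over 6 members (percentile 100), of which Lcn2 and the fibrinogen chain Fgg (1.54) were highest and Plin2 (-0.06) lowest. Interferon-stimulated genes had a median of 0.61, with all 15 members above 0 and Ifi27l2a (1.46) and Irf7 (1.04) highest. Inflammatory cytokine and adhesion genes had a median of 0.57, led by Vcam1, an adhesion molecule for leukocytes (1.42), and Cxcl10 (0.69). Genes of fibrosis and interstitial matrix had a median of 0.47 (percentile 100), with Dcn (1.52) and Col3a1 (1.15) highest and Col6a2 (-0.38) lowest. Corticosteroid receptor target genes had a median of 0.50 (percentile 100), with 11 of 15 members above 0, led by Cdkn1a (1.38) and the metallothionein Mt1 (0.74).

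Among the resident cells of the glomerulus, endothelial markers stood higher in KO control (median 0.35, 16 of 18 above 0, Cdh5 0.70 and Flt1 0.63 highest). So did parietal epithelial cell markers (0.41, Krt18 0.76 highest) and mesangial cell markers (0.21, Art3 0.74). Basement membrane genes (0.36, Nid1 0.83 and Col4a1 0.72) also stood higher. The same held for smooth muscle and pericyte markers (0.35, Myh11 0.68), a list meant to mark cells that a glomerular preparation could carry along. Podocyte markers did not stand apart (median -0.02, 11 of 22 above 0, Npnt 0.49 highest and Tcf21 -0.56 lowest), nor did proximal tubule markers (-0.08) or distal nephron and collecting duct markers (0.01), although the sodium channel subunits Scnn1g (1.21) and Scnn1b (1.20) were each over 2-fold higher. However, the 11 proximal tubule markers with mean intensities under 20000, a subset taken after the results were seen, had a median of -0.27, with 10 below 0. Endoplasmic reticulum stress genes (-0.23) and antioxidant response genes (-0.19, Hmox1 lowest at -1.10) stood lower, while coagulation genes (0.25), cell cycle genes (0.35 over 6 members) and immediate early genes (0.17) stood higher. Of the 16 genes past 2-fold with a further probe set among the brighter ones, 14 had the same direction in it and 10 were past 2-fold in both. With the mean of all probe sets per gene, 32 genes were lower, Slc38a3 had a difference of 0.95, the cell cycle median was 0.61, and the basement membrane (0.08), mesangial (0.01) and smooth muscle (0.18) medians no longer stood apart. Counts depended on signal, with 808 higher and 448 lower when dim genes were kept, where the cell cycle median was 0.81. The brightest 25% held 26 and 7, where the coagulation median was 0.44 and the mesangial median was 0.11. Of the medians that stood apart above and had a value there, only the antioxidant one (-0.13) no longer did.

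**Figure D1:**
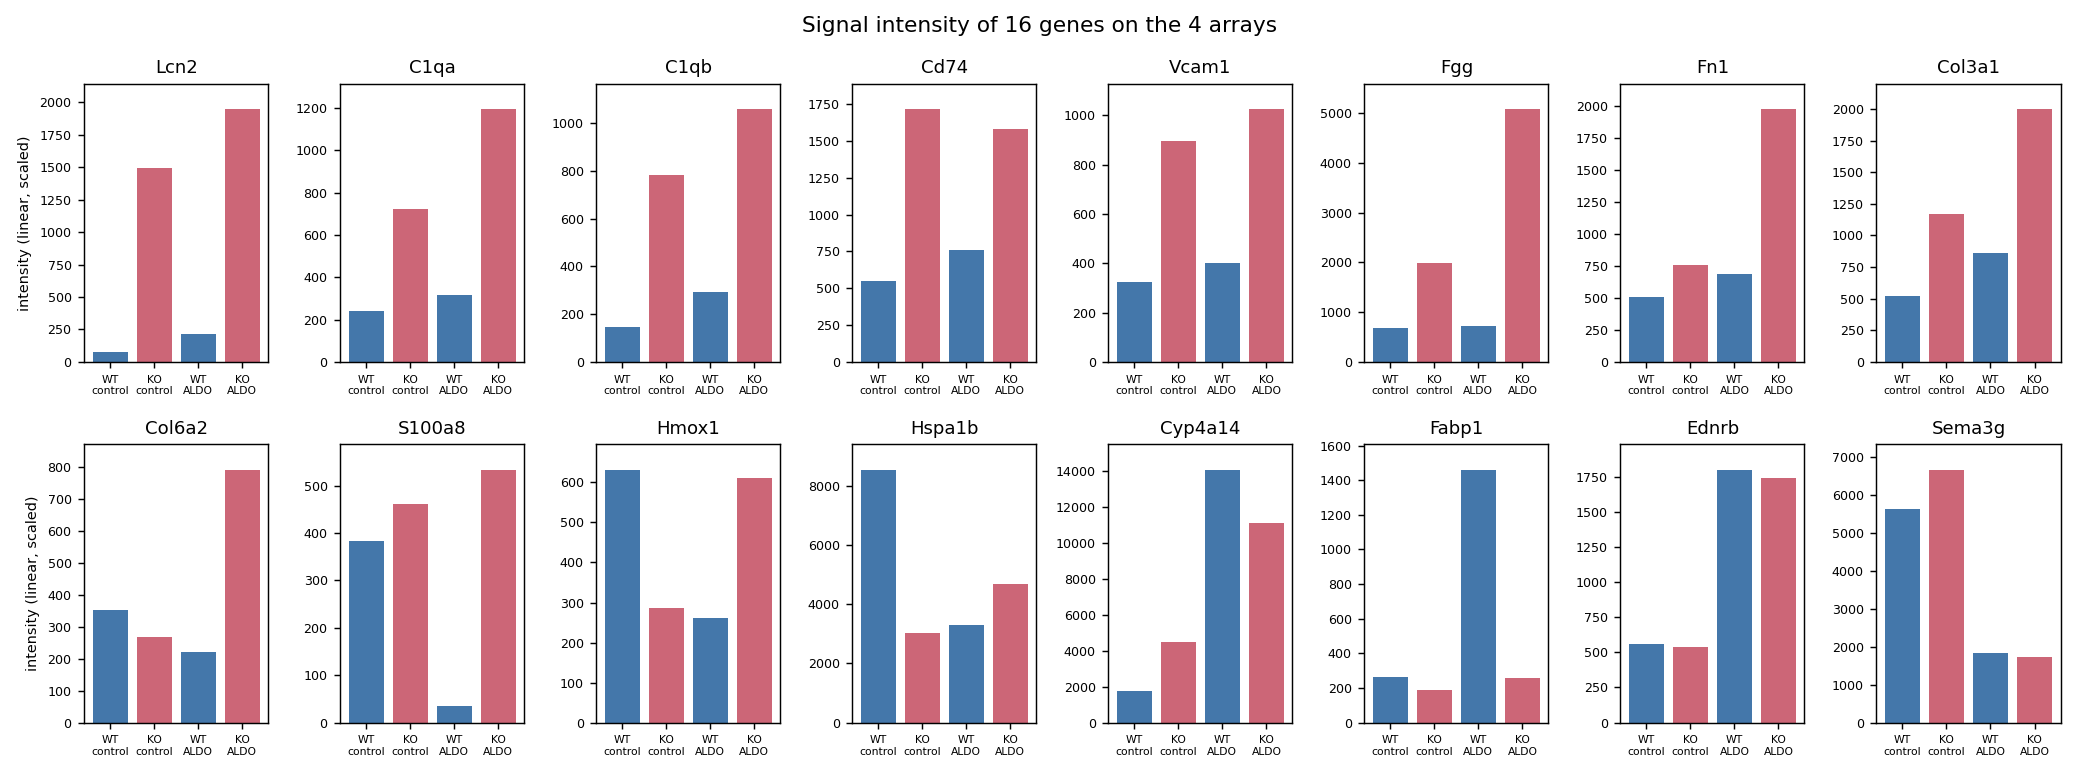
Signal intensity of 16 genes on the 4 arrays, 1 bar per array from 0 on a linear scale (scaled intensity), with WT in blue and KO in red. Lcn2 read 76.5 in WT control and 1497 in KO control, and S100a8 read 34.5 in WT ALDO against 533 in KO ALDO.

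KO ALDO against WT ALDO compared the genotypes under aldosterone and salt. S100a8, a calprotectin subunit of neutrophils and monocytes, had the largest difference, 3.44, with intensities of 34.5 and 533, and it was WT ALDO that stood out, since WT control had 383 and KO control 462. As 34.5 is below that array's median, the size of the difference is uncertain: with a pseudocount of 64 it was 2.60 and no longer the largest. Lcn2 followed (3.07, intensity 218 to 1950), with the fibrinogen chains Fgg (2.79, 721 to 5082) and Fga (1.89), and Socs3, an inhibitor of cytokine signalling (2.66, 180 to 1221). Macrophage and monocyte markers were again higher in KO, with all 15 members above 0, 8 of them past 2-fold, and a median of 1.04 (percentile 100). Fatty acid oxidation genes were lower in KO, with 13 of 15 members below 0 and a median of -0.50 (percentile 0). In all, 115 genes were higher and 32 lower by 2-fold or more.

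The other genes highest in KO ALDO were Wfdc17 (2.96, or 2.45 with a pseudocount of 64, from an intensity of 75.9 in WT ALDO), the matrix glycoprotein tenascin C, Tnc (1.99), Spink8 (1.90), Pamr1 (1.87) and C1qa (1.86). Those lowest were Ces1g (-2.47), the liver-type fatty acid binding protein Fabp1 (-2.44, intensity 1461 to 257), Mcoln3 (-1.57), Igfbp1 (-1.46), Cyp2d9 (-1.35), the ribonuclease angiogenin, Ang (-1.32), the drug efflux pump Abcb1b (-1.30), the carbonic anhydrase Car15 (-1.30), the oxysterol hydroxylase Cyp7b1 (-1.24) and Smlr1 (-1.24).

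Fibrosis and interstitial matrix genes had a median of 0.79, with all 17 members above 0, 5 of them past 2-fold, and Tnc and Col6a2 (1.77) highest. Kidney injury genes had a median of 1.28, and inflammatory cytokine and adhesion genes 0.67 with all 9 members above 0, led by Vcam1 (1.33) and Cxcl10 (1.23). Interferon-stimulated genes had a median of 0.61, led by Ifit1 (1.25) and Gbp3 (1.24), and coagulation genes 0.52, where the plasminogen activator Plau (-0.81) was lowest. Cell cycle genes had a median of 0.75 over 6 members, led by Rrm2 (1.18) and Mcm4 (0.97). Below 0 stood the circadian clock list (median -0.37, Dbp lowest at -0.71) and the cholesterol synthesis list (-0.27, 10 of 13 below 0, Sc5d lowest at -0.75), and the fatty acid list was lowest at Ehhadh (-1.05) and Pdk4 (-1.02). Heat shock (0.15) and endoplasmic reticulum stress genes (0.16) stood slightly higher, with Hspb1 (1.11) leading the first.

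Markers of glomerular cells also stood higher in KO ALDO. Medians were 0.43 for endothelial markers (Sost 0.83 highest), 0.40 for parietal epithelial markers (Krt18 1.03), 0.26 for mesangial markers (Ptn 0.63) and 0.15 for podocyte markers (18 of 22 above 0, Tdrd5 0.66). Basement membrane genes (0.31, all 15 above 0, Col4a1 0.97 and Col4a2 0.96) and smooth muscle and pericyte markers (0.44, Tagln 1.29 highest) stood higher too. Immediate early genes had a median of 0.38, led by Klf6 (0.93). Proximal tubule markers (-0.16), distal nephron markers (0.04), corticosteroid receptor targets (0.10), antioxidant response genes (-0.15), oxidative phosphorylation genes (-0.06) and renin-angiotensin-aldosterone genes (0.17) did not stand apart. Here too the 11 proximal tubule markers with mean intensities under 20000 were lower, with a median of -0.35 and 9 below 0. All 28 genes past 2-fold with a further bright probe set had the same direction in it, 17 of them past 2-fold in both. With dim genes kept, counts were 859 and 425 and the clock median was -0.05 and no longer stood apart. Quantile normalization gave an endoplasmic reticulum stress median of 0.26. The brightest 25% held 35 and 19 genes and heat shock and mesangial medians of 0.04 and 0.13. With the mean of all probe sets Socs3 was at 1.94, endoplasmic reticulum stress at 0.24, cholesterol synthesis at -0.17 and the clock (-0.06), mesangial (0.12) and podocyte (0.14) lists no longer stood apart.

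The genotype differences under the 2 treatments, which share no array, went the same way for many genes. Across the 9097 genes, which are not independent replicates, their Pearson correlation was 0.590 and their Spearman correlation 0.522. Of the 88 and 115 genes higher by 2-fold or more in KO, 49 were shared, against 1.11 for independent lists. Of the 16 and 32 lower genes 3 were shared, against 0.0563. The shared higher genes held Lcn2, Spink8, Cldn4, Ltc4s, Fgg, Socs3, C1qa, C1qb and Cd74, and the 3 shared lower genes were Ces1g, Car15 (-1.14 and -1.30) and Bex1 (-1.10 and -1.10), of which Bex1 was named after its values were seen. With dim genes kept the Pearson correlation was 0.211.

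**Figure D2:**
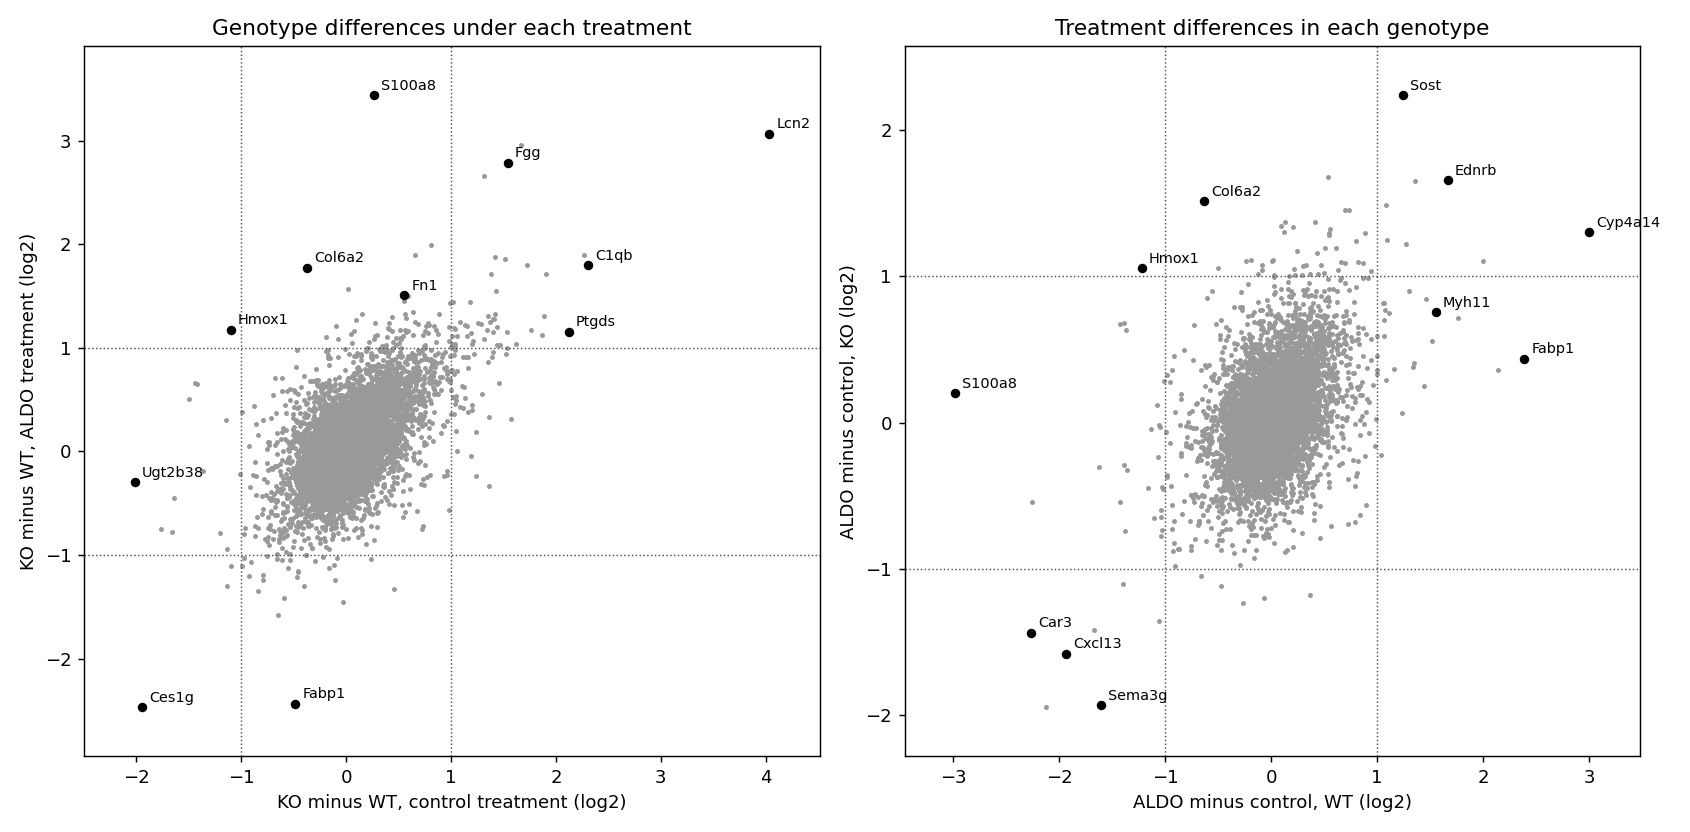
Log2 differences of 9097 genes, 1 point per gene, with KO minus WT under control treatment against the same under ALDO (left) and ALDO minus control in WT against the same in KO (right); dotted lines mark 2-fold and named genes are black. On the left 49 genes lie past 2-fold higher on both axes, and on the right 8 do, with Pearson correlations of 0.590 and 0.405.

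WT ALDO against WT control compared aldosterone and salt with the control treatment in the arrays labelled WT. The highest gene was Cyp4a14, a fatty acid hydroxylase (3.00, intensity 1740 to 14048), followed by Fabp1 (2.39, 266 to 1461), Ang (2.14), Abcb1b (2.00), the retinol dehydrogenase Rdh16f2 (1.76), the endothelin B receptor Ednrb (1.66, 556 to 1799) and the smooth muscle myosin heavy chain Myh11 (1.55). All 15 fatty acid oxidation genes were above 0 (median 0.26, percentile 100), as were all 15 corticosteroid receptor targets (median 0.36, percentile 100), with Pdk4 (1.09), a member of both lists, and Fkbp5 (0.71) highest among the targets. S100a8 was lowest (-2.98), followed by the carbonic anhydrase Car3 (-2.26), Ugt2b38 (-2.26), the chemokine Cxcl13 (-1.94), Jpt1 (-1.63) and the podocyte semaphorin Sema3g (-1.61, intensity 5641 to 1843). In all, 30 genes were higher and 32 lower by 2-fold or more.

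Stc1 (1.52), Rnase4 (1.46) and Cox6b2 (1.44) were the other genes highest in WT ALDO, and Angptl7 (-1.43), Myrf (-1.42), Sugct (-1.39) and Spns3 (-1.39) the other lowest. Ugt2b38, Angptl7 and Myrf were also among the lowest in KO control. Both comparisons use the WT control array, the brightest for these genes, so they are not separate observations. Distal nephron and collecting duct markers stood higher (median 0.43, 14 of 17 above 0), led by the anion exchanger Slc4a1 (0.90) and the vasopressin-regulated water channel Aqp2 (0.66). Cholesterol synthesis genes had a median of 0.27 with all 13 members above 0, led by Lss (0.68) and Fdft1 (0.55). Fibrosis and interstitial matrix genes had a median of 0.43, led by Dcn (0.76) and Col3a1 (0.71), with Col6a2 (-0.64) lowest. Smooth muscle and pericyte markers had a median of 0.41, endothelial markers 0.33 (Sost 1.24 and Tie1 1.07 highest), mesangial markers 0.21 and basement membrane genes 0.14. Macrophage markers had a median of 0.28 with none past 2-fold, kidney injury genes 0.27, interferon-stimulated genes 0.26, immediate early genes 0.32 (Fos 0.94 highest) and clock genes 0.18.

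Heat shock genes stood lower in WT ALDO (median -0.22, 11 of 12 below 0, Hspa1a -1.39 and Hspa1b -1.37), and so did endoplasmic reticulum stress genes (-0.16, Manf -0.85 lowest). Podocyte (-0.04), parietal epithelial (-0.05), proximal tubule (-0.03), inflammatory (-0.10), coagulation (0.06), cell cycle (-0.17), antioxidant (0.01), oxidative phosphorylation (-0.02) and renin-angiotensin-aldosterone (-0.04) lists did not stand apart. Among 18 probe sets of spiked-in control RNA, WT ALDO was lower than WT control by a median of -0.27 and by up to -0.50, the widest range of the 4 pairs of arrays compared. Of 16 genes past 2-fold with a further bright probe set, 14 had the same direction in it and 7 were past 2-fold in both. The mean of all probe sets gave Ang 1.55, Car3 -0.95, Jpt1 -0.70, Sugct -0.79 and medians of 0.42 for kidney injury and -0.32 for endoplasmic reticulum stress. It ended the standing of the smooth muscle (0.08), cholesterol (0.11), clock (0.08), basement membrane (0.09) and cGMP pathway (0.08) lists. Dim genes included, counts were 619 and 471 and the clock median was 0.11 and no longer stood apart. In the brightest 25% counts were 10 and 8, and the macrophage median there was 0.13 and no longer stood apart. With a pseudocount of 64 S100a8, at an intensity of 34.5 in WT ALDO, was at -2.18 and no longer the lowest.

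KO ALDO against KO control made the same comparison in the arrays labelled KO. Sost, which encodes the Wnt inhibitor sclerostin and was on the endothelial list, was highest (2.24, intensity 158 to 806), followed by the tryptophan-degrading enzyme Kynu (1.68), Ednrb (1.66, 540 to 1736), Tmem87a (1.65), the collagen chain Col6a2 (1.51, 267 to 793), the actin-binding protein Tagln (1.45), Rarres1 (1.45), Fga (1.37), fibronectin, Fn1 (1.37, 757 to 1980), and Fgg (1.34). Fibrosis and interstitial matrix genes had a median of 0.73, with 16 of 17 above 0 and Col6a2 and Fn1 highest, and smooth muscle and pericyte markers a median of 0.76, with all 9 above 0 and Tagln and Acta2 (1.19) highest (both percentile 100). Sema3g was lowest (-1.93, intensity 6674 to 1734), followed by Cxcl13 (-1.58), Car3 (-1.44), the steroid dehydrogenase Hsd3b3 (-1.36), Ptgds (-1.23) and Smlr1 (-1.20). In all, 52 genes were higher and 12 lower by 2-fold or more.

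The remaining lowest genes in KO ALDO were Ugt2a3 (-1.18), the cholecystokinin receptor Cckar (-1.12), Sugct (-1.10) and Pzp (-1.05). Immediate early genes had a median of 0.57, with all 15 above 0 and Egr1 (1.16) highest. Coagulation genes had a median of 0.44 with Fga and Fgg highest, kidney injury genes 0.35, endothelial markers 0.38, basement membrane genes 0.23 (Lama2 1.10 highest), corticosteroid receptor targets 0.22 (Cdkn1a 0.66 highest), interferon-stimulated genes 0.22, mesangial markers 0.20 (Fhl2 0.81), heat shock genes 0.19 (Hspb1 1.11), macrophage markers 0.17 (Cd14 0.83), distal nephron markers 0.11 and endoplasmic reticulum stress genes 0.10, all standing higher. Podocyte markers had a median of 0.16 with members on both sides, from Cdkn1c (1.09) and Tcf21 (1.02) to Rhpn1 (-0.98) and Sema3g.

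Fatty acid oxidation (-0.06), cholesterol synthesis (-0.10), clock (-0.06), cell cycle (0.02), inflammatory (0.20), parietal epithelial (0.06), proximal tubule (-0.13), antioxidant (0.07), oxidative phosphorylation (-0.08) and renin-angiotensin-aldosterone (-0.03) lists did not stand apart, although Cyp4a14 was again over 2-fold higher (1.30, intensity 4497 to 11113). Of 16 genes past 2-fold with a further bright probe set, 13 had the same direction in it and 6 were past 2-fold in both. Counts with dim genes kept were 697 and 418 and the kidney injury median 0.56, and the interferon (0.21) and cGMP pathway (0.15) lists then did not stand apart. The brightest 25% held 20 and 6 genes and an endoplasmic reticulum stress median of 0.08 (0.17 with quantile normalization). With the mean of all probe sets the smooth muscle median was 0.45, Fn1 (0.90) and Sugct (-0.64) were within 2-fold and the endoplasmic reticulum stress (0.12 here and 0.08 above) and podocyte (0.08) medians no longer stood apart.

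The treatment differences of WT and KO, which share no array, were also related across genes, with a Pearson correlation of 0.405 and a Spearman correlation of 0.351. Of the 30 and 52 genes higher under ALDO, 8 were shared, against 0.171 for independent lists: Abcb1b, Adm, Cyp4a14, Ednrb, Mgp, Qars, Sost and Tmem87a. Of the 32 and 12 lower genes 7 were shared, against 0.0422, among them Sema3g, Cxcl13, Car3, Hsd3b3 and Sugct. Adm (1.27 in WT and 1.22 in KO), which encodes the vasodilator adrenomedullin, Mgp, which encodes matrix Gla protein (1.09 and 1.25), and Qars were named after their values were seen, and another probe set of Qars had the opposite sign. With dim genes kept the Pearson correlation was 0.109.

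The difference between the ALDO effect in KO and that in WT uses all 4 arrays and was not tested, for want of replicates. S100a8 (3.18, or 2.36 with a pseudocount of 64, since it was dim in WT ALDO), the heme-degrading enzyme Hmox1 (2.28), Col6a2 (2.15), Angptl7 (2.10), Hspa1a (2.07) and Hspa1b (2.01) had the largest positive differences. Fabp1 (-1.95), Ang (-1.78), Cyp4a14 (-1.70), Ugt2a3 (-1.54), the water channel Aqp4 (-1.47, intensity 189, 467, 339 and 285) and St7 (-1.47) had the largest negative ones. Fatty acid oxidation genes had a median of -0.42 (percentile 0), with 13 of 15 below 0, and cholesterol synthesis genes a median of -0.33 (percentile 0), with 11 of 13 below 0 and Insig1 (-0.89) and Lss (-0.78) lowest. Fibrosis and interstitial matrix genes had a median of 0.28, with 14 of 17 above 0 and Col6a2 and Tnc (1.18) highest. In all, 54 genes had a difference of effects past 2-fold in the positive and 30 in the negative direction.

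Heat shock genes (median 0.49), endoplasmic reticulum stress genes (0.38, Sdf2l1 1.02 and Manf 1.01 highest), immediate early genes (0.37, Egr1 0.73), podocyte markers (0.20, Tcf21 0.58) and parietal epithelial markers (0.19, Cldn1 0.32) stood higher in this difference. Clock genes (-0.20), corticosteroid receptor targets (-0.18, Pdk4 -0.80 and Tsc22d3 -0.52 lowest) and distal nephron markers (-0.16, Scnn1b -0.75 lowest) stood lower. Macrophage markers (0.02), kidney injury genes (-0.11), interferon-stimulated genes (0.00), inflammatory genes (0.16), coagulation genes (0.06), endothelial (0.08), smooth muscle (0.13) and mesangial markers (0.07), basement membrane genes (0.12), proximal tubule markers (-0.09), oxidative phosphorylation genes (-0.08), renin-angiotensin-aldosterone genes (0.10), cGMP pathway genes (0.06), cell cycle genes (0.09) and antioxidant genes (0.05) did not stand apart. Probe sets bore these differences out least: of 18 genes past 2-fold with a further bright probe set, 13 had the same direction in it and 2 were past 2-fold in both. Counts were 1068 and 936 with dim genes kept, 12 and 9 in the brightest 25% and 83 and 50 with the mean of all probe sets, which gave Col6a2 1.37, Ang -1.15 and a cholesterol median of -0.19. The podocyte and parietal medians, both 0.12, then no longer stood apart. In the brightest 25% the clock median was -0.35, and parietal markers there (0.10) and immediate early genes with dim genes kept (0.16) also did not stand apart.

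**Figure D3:**
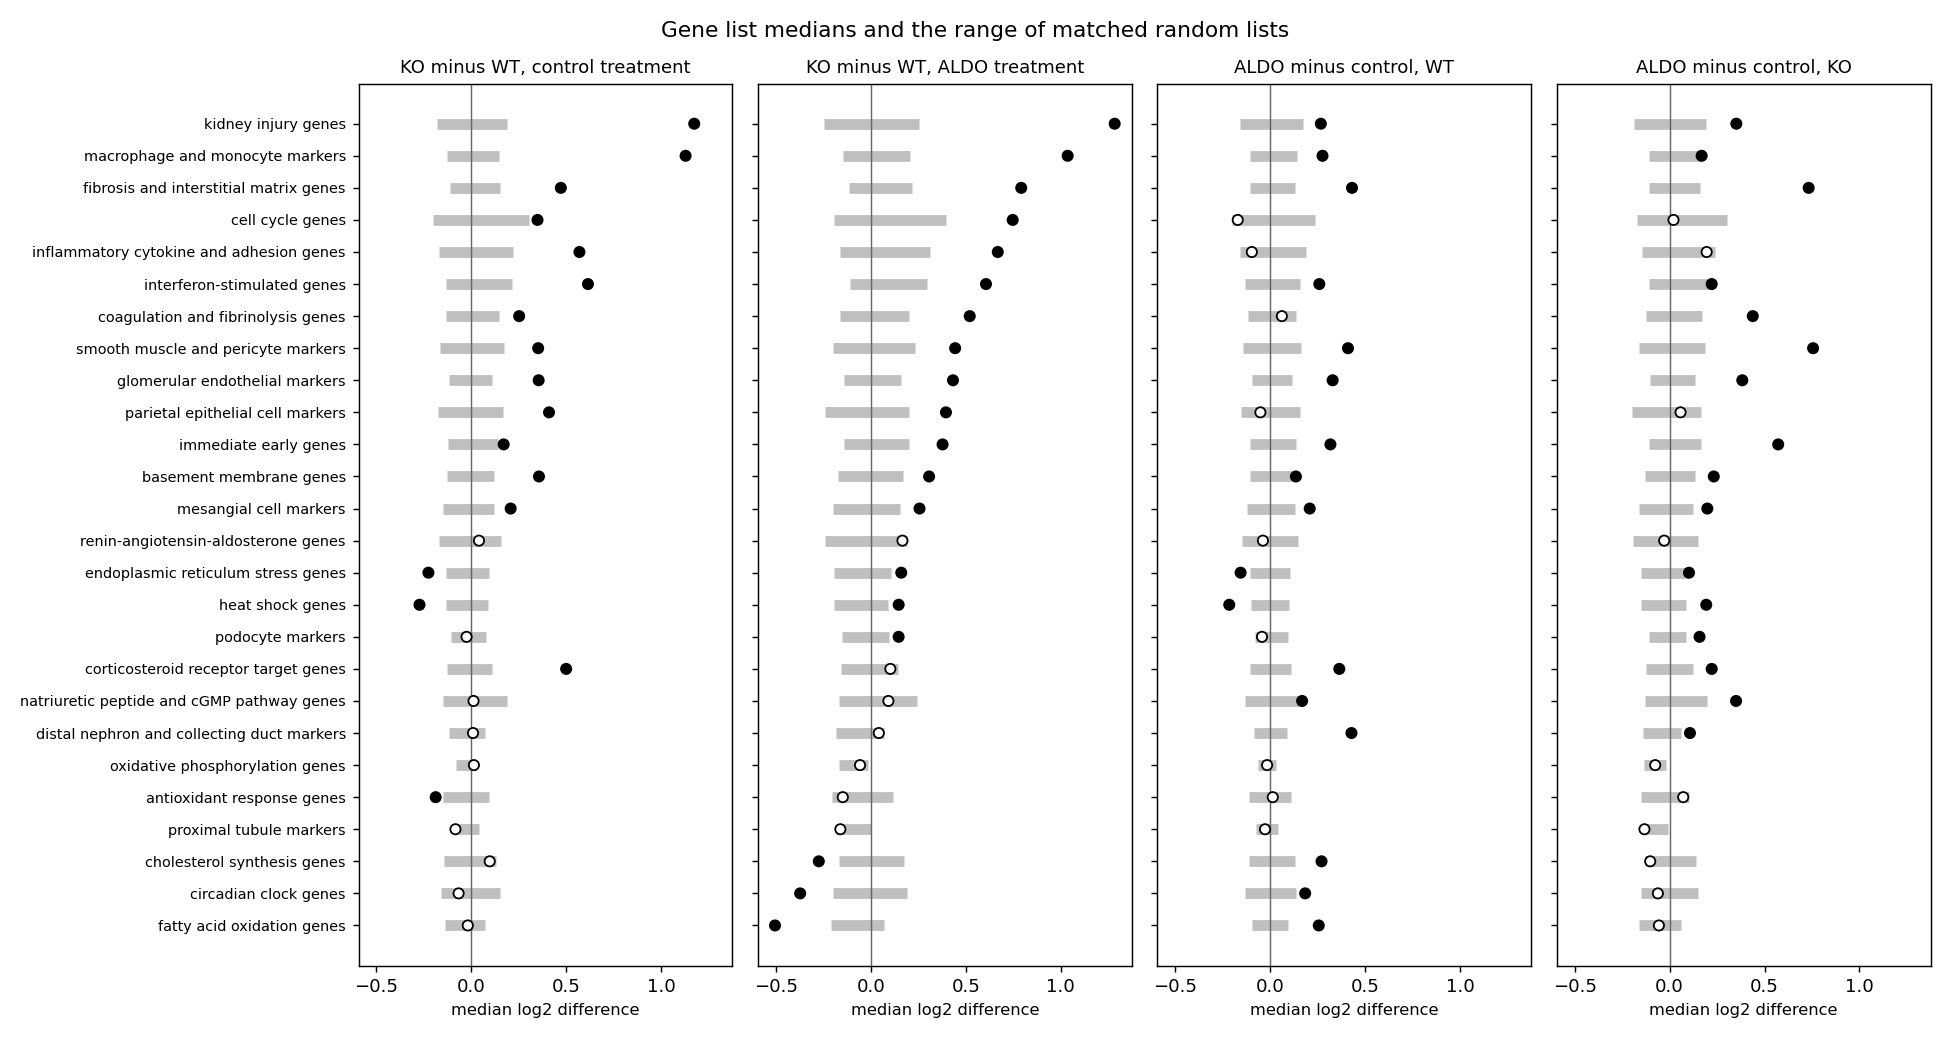
Median log2 difference of 26 gene lists in the 4 pairs of arrays (x axis), 1 point per list, filled where the list stood apart, with grey bars for the central 95% of 10000 matched random lists. Macrophage and monocyte markers lie at 1.13 and 1.04 between genotypes and at 0.28 and 0.17 between treatments.

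Transcripts of tubules were bright in all 4 arrays of this glomerular RNA. The androgen-regulated proximal tubule gene Kap had intensities of 49489, 48508, 43854 and 45032, and Umod, which encodes uromodulin of the thick ascending limb, had 30426, 30615, 27142 and 29223, in the order WT control, KO control, WT ALDO and KO ALDO. Kap had the highest intensity of all probe sets on the WT control, KO control and KO ALDO arrays. Differences of the genes and lists above may therefore come from tubules as well as from glomerular cells. Of the neutrophil markers 2 were counted, of the lymphocyte markers 1, of the erythroid genes 0 and of the NADPH oxidase genes 4, so these 4 lists were not placed. For the erythroid list this does not mean dim transcripts. Globin was read by 4 bright probe sets (intensities from 1298 to 19737) that each match several globin genes and were therefore not used for genes. Cybb, the catalytic subunit of the phagocyte oxidase, was higher in KO by 0.92 under control treatment and by 0.94 under ALDO, while the other 3 were slightly lower: Cyba (-0.19 and -0.07), Nox4 (-0.21 and -0.19) and Rac1 (-0.05 and -0.02). The lymphocyte marker Ighm differed by 0.35 and 0.15. The ratio of the 3' to the 5' probe set was 1.86, 1.67, 1.87 and 1.61 for beta-actin and 0.785, 0.741, 0.778 and 0.744 for Gapdh in the same order, lower in both KO arrays than in the WT array of the same treatment.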

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

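All tests of explanations in this part were chosen after the results were seen. Heat shock genes went in opposite directions in the compared pairs of arrays, and the difference between them was not tested: the median was -0.22 for ALDO against control in WT and 0.19 in KO, and -0.27 for KO against WT under control treatment and 0.15 under ALDO. The median over these genes of each gene's difference between the ALDO effects was 0.492, the same value seen from either side. Endoplasmic reticulum stress genes did likewise (-0.16 and 0.10, and -0.23 and 0.16), with a median of 0.382 over the genes' differences, also untested. In the brightest 25% of genes the heat shock median for KO against WT under ALDO (0.039) and the endoplasmic reticulum stress median for ALDO against control in KO (0.08) no longer stood apart, nor did the latter with the mean of all probe sets (0.12). Hmox1 was lower by 2-fold or more under ALDO in WT (-1.22) and higher in KO (1.06), and lower in KO under control treatment (-1.10) and higher under ALDO (1.18), an untested difference of 2.28. With 4 arrays these pairs are the same contrast seen from either side, so WT control and KO ALDO were the brighter arrays for these genes.

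For the heat shock genes, the signal of single probe sets is argued against, since the next-brightest probe sets of 8 members also gave WT control a higher value than the mean of KO control and WT ALDO, by a median of 0.220, close to 0.218 for the brightest ones. Handling stress of the WT control glomeruli that also raises immediate early genes is argued against by those genes, whose median in WT control lay -0.170 from the same mean, although treatment or genotype may have raised them in the other arrays. Such handling of KO ALDO, the other bright array, was not tested. Immediate early genes were higher there by medians of 0.57 against KO control and 0.38 against WT ALDO. Handling that raises heat shock genes alone, a shared preparation day of WT control and KO ALDO, and an effect of genotype on the response to ALDO all stay open and untested. No replicate array separates them.

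Outside the named genes, 10092 probe sets had no single gene name, and 1381 of these were as bright as the genes counted. Of them, 5 were higher by 2-fold or more in KO under both treatments and 1 was lower under both, with the WT array of the same treatment as the control.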

How the results depend on the processing

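No paired analysis was possible because the groups compared share replicate number 1 only, and no result comes from a test. An additive fit of genotype and treatment over the 4 arrays could be made, but its residual would be the difference of effects itself, with no separate measure of error. No list median that stood apart and no named gene changed sign under the alternatives that gave it a value. Median centring and a pseudocount of 1 left all counts, correlations and list medians within the bounds set for a shift, and quantile normalization and a pseudocount of 64 left all counts and correlations within them. Of 544 alternative values of the 80 list medians that stood apart, 473 stayed within the spread of random lists' medians and 71 moved past it, and 31 no longer stood apart. In the brightest 25% of genes 16 of those medians had no value. Of 574 alternative values of named genes 552 stayed and 22 moved. Where a value moved, the cause was not tested, except that keeping dim genes adds genes and the brightest 25% leaves fewer to count. Signal over background limits the results: with dim genes kept, more genes passed 2-fold and in 3 of the 5 comparisons their probe sets went the same way less often by more than the bounds set.

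With dim genes kept, genes higher and lower by 2-fold or more were 808 and 448 for KO against WT under control treatment, 859 and 425 under ALDO, 619 and 471 for ALDO against control in WT, 697 and 418 in KO, and 1068 and 936 for the difference of effects. The next-brightest probe set then went the same way in 57.9%, 63.8% and 52.8% of genes in the first 3 of these, against 87.5%, 100% and 87.5%. Pearson correlations were 0.109 for the ALDO effects and 0.211 for the genotype differences. For KO against WT under control treatment, moved medians were cell cycle 0.81, fibrosis 0.56, kidney injury 1.28 and macrophage 1.01. For KO against WT under ALDO, moved medians were clock -0.049, coagulation 0.40, inflammatory 0.86 and macrophage 1.13. For ALDO against control in WT, the moved median was clock 0.11. For ALDO against control in KO, moved medians were kidney injury 0.56 and cGMP pathway 0.15. For the difference of effects, moved medians were immediate early 0.16 and parietal 0.28.

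In the brightest 25% of genes, the counts in the same order were 26 and 7, 35 and 19, 10 and 8, 20 and 6, and 12 and 9. Next-brightest probe sets went the same way in 100% of genes for KO against WT under control treatment, 50% for ALDO in WT and 100% for the difference of effects. The correlations were 0.478 and 0.647. For KO against WT under control treatment, moved medians were coagulation 0.44, macrophage 1.01 and mesangial 0.11. For KO against WT under ALDO, moved medians were basement membrane 0.39, coagulation 0.67, heat shock 0.039, immediate early 0.48 and mesangial 0.13. For ALDO against control in WT, moved medians were distal nephron 0.38, heat shock -0.16 and macrophage 0.13. For ALDO against control in KO, moved medians were coagulation 0.61, fibrosis 0.66, immediate early 0.38, cGMP pathway 0.25 and podocyte 0.23. For the difference of effects, moved medians were clock -0.35, endoplasmic reticulum stress 0.30 and fibrosis 0.20.

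With the mean of all probe sets, 32 genes were lower in KO control, and 83 and 50 had a positive or negative difference of effects past 2-fold. The correlations were 0.316 and 0.514. For KO against WT under control treatment, moved medians were antioxidant -0.28, basement membrane 0.075, cell cycle 0.61, corticosteroid target 0.37, fibrosis 0.36, heat shock -0.39, kidney injury 1.003, mesangial 0.014 and smooth muscle 0.18. For KO against WT under ALDO, moved medians were cell cycle 0.60, cholesterol -0.17, clock -0.064, coagulation 0.41, endoplasmic reticulum stress 0.24, fatty acid -0.34, fibrosis 0.69, immediate early 0.47, inflammatory 0.79, macrophage 1.23, mesangial 0.12 and parietal 0.51. For ALDO against control in WT, moved medians were cholesterol 0.11, clock 0.085, distal nephron 0.32, endoplasmic reticulum stress -0.32, fatty acid 0.18, heat shock -0.27, kidney injury 0.42, cGMP pathway 0.076 and smooth muscle 0.083. For ALDO against control in KO, moved medians were podocyte 0.085 and smooth muscle 0.45. For the difference of effects, moved medians were cholesterol -0.19, fatty acid -0.34 and podocyte 0.12. Named genes that moved by over 1.5-fold were Slc38a3 (0.95 in KO control), Socs3 (1.94 in KO ALDO), Ang (1.55), Car3 (-0.95), Jpt1 (-0.70) and Sugct (-0.79) in WT ALDO, and Col6a2 (1.37) and Ang (-1.15) in the difference of effects.

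Quantile normalization moved 3 medians: endoplasmic reticulum stress to 0.26 for KO against WT under ALDO and 0.17 for ALDO in KO, and fatty acid to -0.42 for KO against WT under ALDO. A pseudocount of 64 moved the fibrosis median for ALDO in KO to 0.66 and gave S100a8 2.60, -2.18 and 2.36 for KO against WT under ALDO, ALDO in WT and the difference of effects. Medians that moved little and yet no longer stood apart included basement membrane for ALDO in WT (0.13 with quantile normalization, 0.11 with dim genes kept, 0.084 in the brightest 25%) and interferon for ALDO in KO (0.16 with quantile normalization and 0.21 with dim genes kept).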

Other observations

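All tests in this part, and its lists of acute-phase, PPAR-alpha, male-biased, female-biased and endothelin genes, were drawn up after the values of their members had been seen, so none of them is independent evidence. Acute-phase and STAT3-linked genes were higher in KO, with a median of 0.62 under control treatment and 1.01 under ALDO over 16 measured genes, 8 of them past 2-fold under ALDO. Besides Socs3 and the fibrinogen chains, the oncostatin M receptor Osmr (0.59 and 1.16), ceruloplasmin, Cp (0.87 and 1.13), the transcription factor Cebpd (0.98 and 1.06) and the TWEAK receptor Tnfrsf12a (0.56 and 1.46) were higher, while complement factor B, Cfb (-0.34 and -0.43), was lower. The median for ALDO against control was 0.65 in KO and 0.12 in WT. The list held genes already named above, such as Lcn2, Socs3, Fgg and Fga. Its 12 measured members outside the fixed lists and named genes had genotype medians of 0.47 under control treatment and 0.82 under ALDO. Of these members 0 and 4 were past 2-fold higher. Their median for ALDO against control was 0.50 in KO and 0.20 in WT. Of a group of endothelin, nitric oxide synthase 1 and prostaglandin genes, too small to be placed with 4 measured members, the prostaglandin synthases Ptges (1.53 and 1.15) and Ptgds (2.12 and 1.16) were higher in KO, Edn1, which encodes endothelin, was at 0.59 and 0.55 and Ednrb at -0.04 and -0.05, while the cyclooxygenase Ptgs2 was dim (-1.62 and 0.42).

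PPAR-alpha targets outside the fatty acid oxidation list had a median of 0.28 for ALDO against control in WT, with 15 of 16 above 0, and of -0.01 in KO. Eci1 (0.99 and 0.02), Angptl4 (0.84 and 0.02), Acaa1b (0.71 and 0.12) and Vnn1 (0.53 and -0.03) followed that order, and Acot3 (0.81 and 0.93) did not. Genes known to be more abundant in male than in female mouse kidney had medians of -0.28 under control treatment and -0.48 under ALDO for KO against WT over 15 measured genes. Cndp2 (-0.96 and -0.74) was lowest under control treatment, and Cyp2d9 (-0.84 and -1.35), Cyp7b1 (-0.80 and -1.24), Acsm3 (-0.80 and -1.19) and Slc7a13 (-0.55 and -1.13) were lowest under ALDO. Kap (-0.03 and 0.04), Cyp2e1 (0.08 and -0.03), Acsm2 (0.02 and 0.00) and Cyp4b1 (-0.02 and -0.25), all with intensities above 20000, were close to equal or less low, and whether such bright probe sets saturate was not tested. With mean intensities under 20000, Odc1 (0.10 and -0.39), Cyp2j13 (-0.22 and -0.13) and Timd2 (-0.18 and -0.29) also lay above the list medians. The less changed members were thus not only the brightest ones. The list was also lower for ALDO against control, with medians of -0.17 in WT (11 of 15 below 0) and -0.34 in KO (all 15 below 0). Its difference of effects (-0.12) did not stand apart. Lower values under ALDO were thus seen in both genotypes, and whether the fall was larger in KO was not tested. Of 4 measured genes more abundant in females, Aadat (-0.66 and -1.04) was lower and the others, Cyp4a14 (1.36 and -0.34), Slc22a29 (-0.52 and 0.04) and Gstp1 (-0.21 and -0.06), went no common way.

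The immune cell markers were higher in both KO arrays. A larger share of tubulointerstitial tissue with all its tubules is argued against as the whole cause, since the highest of the 4 medians of proximal and distal tubule lists between genotypes was 0.0426, against 1.04 for the lower macrophage median. Without the proximal tubule markers above an intensity of 20000, the other 11 had medians of -0.271 under control treatment and -0.350 under ALDO. Genes of the distal nephron and collecting duct went both ways, however, some of them outside the list, with Scnn1g (1.21 and 1.06), Rhcg (1.40 and 1.16), Cldn4 (1.91 and 1.72) and Krt7 (1.003 and 1.008) higher in both KO arrays and Aqp3 (-0.43 and -0.93) and Fxyd4 (-0.53 and -0.99) lower, so interstitial tissue without a like share of tubules stays open. Residual blood with its red cells is argued against as the whole cause by 4 probe sets that each match several globin genes. They were bright on all arrays, and their highest KO minus WT difference was 0.461. Their medians were -0.14 under control treatment and 0.37 under ALDO. Globin probe sets do not measure leukocytes, so more blood leukocytes without a like share of red cells were not tested. More macrophages in KO glomeruli or around them, a higher content of these transcripts per cell, RNA quality, whose 3' to 5' ratios were lower in both KO arrays (beta-actin 1.67 and 1.61 against 1.86 and 1.87), and a difference between individual mice or preparations stay open as well.

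Fatty acid oxidation genes were higher in WT ALDO than in WT control and lower in KO ALDO than in WT ALDO, while KO ALDO against KO control had a median of -0.06 that did not stand apart. A lower share of proximal tubule RNA is argued against as the whole cause of the difference of effects, since 11 proximal tubule markers under an intensity of 20000 had a median of -0.114 there, against -0.419 for the fatty acid genes (-0.34 with the mean of all probe sets). It stays open for the lower value in KO ALDO than in WT ALDO, where the same markers had -0.350 (-0.16 for the whole list of 19), against -0.50 for the fatty acid genes (-0.34 with that mean). Time of day at collection cannot be told apart from the groups: clock output genes were lower in KO ALDO than in WT ALDO (median -0.453 over 5 genes), but of the core genes expected to move the other way only Clock was bright enough to count (0.10), and Arntl, below that level, was at 0.98. The whole clock list, which also holds those core genes, had -0.37 there. It no longer stood apart with dim genes kept (-0.05) or with the mean of all probe sets (-0.06). A smaller rise of PPAR-alpha activity under ALDO in KO than in WT is a candidate explanation. Among 14 target genes outside the fixed lists and named genes, the median difference of the ALDO effect was -0.262 (percentile 0.01 of random lists). Their medians for ALDO against control were 0.281 in WT and -0.029 in KO. Between KO ALDO and WT ALDO they had -0.440, against -0.350 for the 11 proximal tubule markers. That pair does not separate this explanation from a lower share of proximal tubule RNA. Food intake, which would act through the same genes, was not measured here. The medians of 0.281, -0.262 and -0.440 all use the single WT ALDO array. A difference of that preparation or its mice therefore stays open as well. Angptl4, for example, had an intensity of 2772 in WT ALDO, against 1547 in WT control, 1511 in KO control and 1534 in KO ALDO.

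A stronger acute-phase response in KO kidneys under ALDO is a candidate explanation for the fibrinogen and Socs3 differences. The 12 list members outside the fixed lists and the named genes had a median of 0.816 between KO ALDO and WT ALDO (percentile 100). As the list was drawn up after its values were seen, that percentile is no support of its own. The same members already had a median of 0.474 under control treatment. Acute-phase genes such as Saa1, Saa2, Serpina3n and Hp were too dim to count. A difference between individual mice or preparations stays open. The lower tubular enzymes in KO have a pair of candidate explanations that stay open. The first is a weaker male-biased gene program. Measured members of that list outside the fixed lists and the named genes numbered 9. Their medians were -0.280 under control treatment (percentile 0.03) and -0.478 under ALDO (percentile 0). The other is a lower share of proximal tubule RNA in the KO preparations, since 11 proximal tubule markers under an intensity of 20000 had medians of -0.271 and -0.350, although the whole list of 19 had -0.08 and -0.16 and did not stand apart. The tests do not separate these, and androgen levels were not measured here. These hypotheses come from the arrays they were tested on.

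Passenger alleles flanking the targeted gene could account for some genotype differences that do not depend on treatment. Among the 100 counted genes nearest to Npr1 in gene order, 6 differed by 1.5-fold or more in the same direction under both treatments: Syt11 (0.74 and 0.73), Rusc1 (0.81 and 0.74), Muc1 (0.99 and 0.67), S100a4 (0.86 and 1.06), Ctss (0.99 and 1.44) and Adamtsl4 (0.67 and 0.78). Ctss is also on the macrophage and monocyte list, whose measured members were all higher in KO under both treatments. The median window of 100 genes held 3, and 91.7% of 7101 windows held fewer than 6, which leaves the explanation of passenger alleles undecided. The strain background of the mice is not given in the sources used here.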
